A study of Mus musculus with 140 samples.

How the data were processed

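Gene expression was measured in 7 brain regions of adult C57BL/6J mice, aged 56 to 80 days, under 5 conditions of sleep and waking, with 4 arrays for each of the 35 combinations of region and condition, 140 arrays in all. Per the labels' protocols, each region was isolated by laser microdissection from 10 µm sections stained with cresyl violet. RNA was purified, 5 ng of total RNA was put through a linear amplification in successive rounds, and the biotin-labelled product was hybridised to one-colour CodeLink mouse arrays. Group, region, condition, time of day and specimen were taken from the labels of each sample. The specimen numbers named 28 animals, each of which gave tissue to between 1 and 7 regions, and 3 arrays of the tuberomammillary region pooled 2 animals. Within a region each array came from a different animal or pool, so the spread between arrays holds the differences between animals together with those of dissection, amplification and hybridisation. Replicate numbers within a group followed accession order and were not used to pair arrays, although in some regions, such as the orbital cortex, arrays of the same number often shared a scan session and a decade of the specimen number.

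The deposited scanner files give, per the file headers, a linear intensity for each of 35587 spots per array, as the mean of the spot pixels and the median of the local background, with the scanner software's quality codes and its own background-subtracted value. That value equalled spot mean minus background median in all files, to within 5e-12, and no normalization across arrays had been applied. What else the submitters did to the values is not given in the sources used here. A table of processed values of the same 140 arrays, on a linear scale with column medians between 18.2 and 20.3, was also deposited by the authors. Its entries matched 34967 probes by spot position, and entry means over all columns correlated with probe means over all arrays at r = 0.999. Its columns, however, were closest to the array they are named for in 3 of 140 cases. For 119 columns the closest array belonged to another region than the column's name. The correlation of a column with the array of the same name had a median of 0.922, against 0.992 for the closest array. Each of the 140 columns had a different closest array, at the place given by the order of the slide labels. Its scale appears linear and common to all columns, while the method behind it stays unknown. Columns were not reassigned by order or by values, and the table was used in no comparison.

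Starting from the scanner files, background was corrected with normexp (saddle-point fit, offset 50, all spots) and log2 was taken. The 620 control spots and the 0.65% of probe spots with a quality code for contamination, irregular shape or masking were then removed, and the 140 arrays were quantile-normalized together. Saturated spots, 4116 over all arrays, were kept. Of 34967 probes per array, 14763 carried a RefSeq accession that matched 1 symbol in the RefSeq gene table used here, without versions on both sides, giving 13971 genes. Probes with other identifiers were kept unnamed and tested separately. A gene was represented by its probe with the highest mean over the 140 arrays. A probe counted as detected on an array where the scanner software did not mark it as near background, and a gene entered a fit if it was detected on at least 4 arrays of that fit. Detected probes made up 27.6% to 69.5% of probes per array, with a median of 52.35%. The local background had array medians between 44 and 57 intensity units, against array medians of the background-subtracted signal between 9.4 and 62.4. The precision of each value is limited by the number of arrays. A left-out spot took the mean of its group's remaining spots with 1 residual degree of freedom less.

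Tests were made with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of the data.table package. Within a region, lmFit and eBayes were applied to the 20 arrays of that region with 1 mean per condition. Across regions, all 140 arrays were fitted with 35 group means and the animal as a random block (duplicateCorrelation on all 11982 tested genes, consensus correlation 0.00683), and the effect was the mean of the 7 differences within regions. In earlier runs the correlation came from a random draw of genes, and 2 such runs gave 25 and 20 genes for deprivation. The design fixed beforehand named no subset, so all tested genes were then used, a decision taken after the draws had been seen but before the counts from all genes were known. Counts from 10 draws are given with the other alternatives. Differences between regions in the effect of deprivation were tested with a limma F test in the same fit. All tests were two-sided. P values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. Where a gene was detected on no array of one group, its fold is a lower bound, taken as the mean of the brighter group against the mean, per array, of the higher of the lowest detected signal and the probe's own value.

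A set of 29 gene lists, covering pathways, cell types and region markers, was fixed before the data were examined, as were the design of each comparison, the choice of named genes and the alternatives other than those chosen after seeing the data. The latter were the scan session as a block, the exclusion of the dimmest arrays, the exclusion of arrays outside the locus coeruleus with a signal of its marker Slc6a2, the detected share of each array as a covariate and the draws of genes for the animal correlation. All tests of spontaneous waking within the suprachiasmatic region were also chosen after seeing the data. Lists with at least 3 measured members were tested, 28 of them across regions, with camera per region (preset correlation 0.01) and cameraPR on the moderated statistics across regions, each again with an estimated correlation. A list's shift is the mean log2 difference of its members, and the test sets their statistics against those of all other genes. List scores per animal, the mean of centred members over the animal's regions, were compared with exact permutation tests of animals. In these an animal with 1 region counted as much as an animal with 7. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in all 7 regions for deprivation, the 5 and 5 by the same criterion for the other comparisons across regions, the 3 and 3 or 2 and 2 within a region for deprivation or recovery, the 10 smallest p of the F test, up to 4 called members of a list, and 16 genes of interest named beforehand.

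The fits were tested on simulated data with the real region means and the real spread of each gene, and without missing spots. No condition effect was present except in the changed genes, 50 for each of 4 sizes. All sizes were changed in the same run, which eases the Benjamini-Hochberg threshold, so recovery would be lower where few genes change. The noise was drawn independently for each gene and array, so correlation within lists, animals or scan sessions was not represented. Across regions, 76% of genes changed by 0.5 (log2) and 98% of those changed by 1 were recovered for deprivation among 11982 genes. Within single regions, where 9479 to 10247 genes were tested, between 2% and 16% of genes changed by 0.5, between 34% and 64% of those changed by 1 and between 80% and 92% of those changed by 2 were recovered. Unchanged genes called in a run numbered 2 for deprivation across regions and up to 15 within single regions. The F test over regions recovered 22 of 50 genes changed by 1 in a single region. A list of 20 genes shifted by 0.2 was called at adjusted p = 2.44e-18, with 0 of the other lists called.

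The arrays were scanned in 12 sessions, and 34 of 40 combinations of region and session held more than 1 condition, so the scan session was also fitted as a block and effects were computed within sessions. The slide series, read from the slide labels, had 4 values. The decade of the specimen number, with 7 values, was fitted as a replicate block, although the labels do not say that it marks a cohort. Other alternatives were an offset of 16, median scaling, quantile normalization within each region, no filter on dim probes, every probe, array weights, 1 value per animal, exclusion of the pooled arrays and exclusion of each animal or replicate in turn. Probe names depend on the RefSeq table used, and genes without a match were not analysed here by name.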

Results

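Gene expression was measured in 7 laser-dissected brain regions of C57BL/6J mice after 6 h of sleep deprivation (SD, ZT6), after 4 h of recovery sleep (RS, ZT10), during spontaneous waking at night (W, ZT18), and in undisturbed controls at ZT6 (SDC) and ZT10 (RSC). The regions were the hypocretin area of the hypothalamus, the locus coeruleus (LC), the dorsal entorhinal cortex (ENT), the orbital cortex (ORB), the posteromedial cortical amygdala (COApm), the suprachiasmatic region (SCh) and the ventral tuberomammillary nucleus (TMN). Each of the 35 groups of region and condition held 4 arrays, 140 in total, from 28 animals that each gave tissue to between 1 and 7 regions. Changes common to the brain were tested across all 7 regions with animals as blocks, which covered 11982 genes, and changes of single regions were tested on 4 against 4 arrays. The animal correlation, 1 value for all genes, was 0.00683, so the fit across regions treated arrays of the same animal as nearly independent.

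The dissections carried the transmitter and peptide genes of their nuclei. Hcrt, which encodes the wake-promoting hypocretin peptides, stood at 14.84 (log2) in the hypocretin area and between 6.57 and 7.66 in the other 6 regions, and its spots were saturated there. The noradrenaline transporter Slc6a2 (14.66) and the noradrenergic transcription factor Phox2a (10.00) had their highest means in the LC. Slc6a2 was also detected on 22 of 120 arrays of other regions, with 6 of these over 8 and an array of the ZT10 controls of the hypocretin area at 11.31. Hdc, which makes histamine, reached 14.63 in the TMN, and a second level of 10.97 in the SCh stood well above the 6.22 to 6.80 of the remaining regions. Vip (10.07), Avp (11.24) and Grp (11.57), the peptides of the circadian clock nucleus, marked the SCh. The cortical transcription factor Neurod6 was at 8.01 in ENT and 7.92 in ORB but at 6.16 in COApm, no higher than in the hypothalamic regions, whereas the glutamate transporter Slc17a7 stood at 10.18 in ENT, 10.52 in ORB and 10.75 in COApm.

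**Figure D1:**
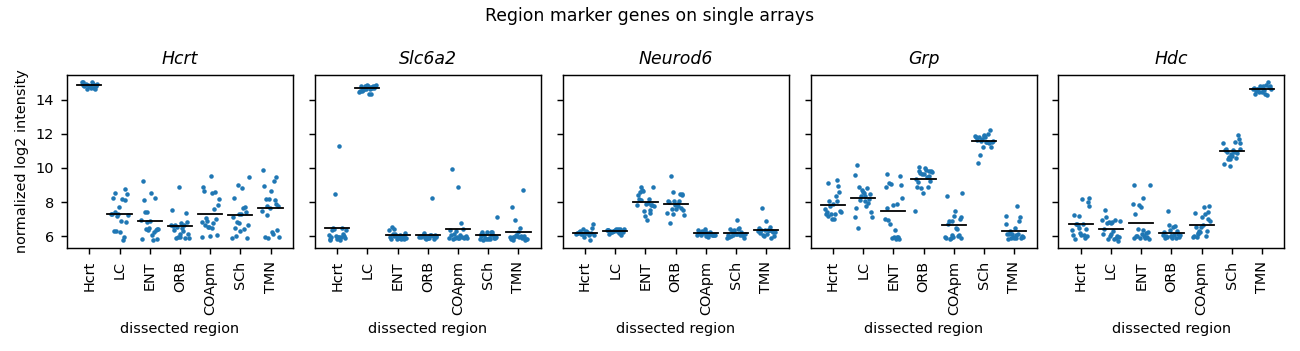
Expression (log2 intensity, vertical axis) of 5 marker genes by region (Hcrt on the horizontal axis is the hypocretin area), with points for arrays and bars for means. Hcrt at 14.84 in the hypocretin area and Hdc at 14.63 in the TMN stood out, and Hdc at 10.97 in the SCh lay between the TMN and the other regions.

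Sleep deprivation moved a small set of genes, most of them in the same direction in all 7 regions. The glucocorticoid-induced gene Tsc22d3, the cell-cycle inhibitor Cdkn1a and the stress gene Creld2 rose, while the clock-output gene Dbp, the cold-inducible RNA-binding gene Cirbp, the Notch target Hes5 and the oligodendrocyte gene Opalin fell. Across regions 20 genes passed, 13 higher and 7 lower than in SDC, and 772 genes had an unadjusted p under 0.05 where chance gives 599. The split was 6 higher and 2 lower when arrays were scaled to a common median.

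Tsc22d3, a glucocorticoid-induced leucine zipper gene, gave the firmest rise (log2 0.67, SE 0.08, 1.59-fold, adjusted p = 1.4e-10), with region values from 0.28 to 0.96. Cdkn1a rose most (1.04, SE 0.18, 2.06-fold, adjusted p = 0.000238), although its region values ran from 0.03 to 1.80. Creld2, an endoplasmic reticulum (ER) stress gene, rose 1.72-fold (0.78, SE 0.13, adjusted p = 0.000238), and Chordc1, a partner of the chaperone Hsp90, rose 1.65-fold (0.73, SE 0.16, adjusted p = 0.0116). Fam107a, an actin-binding gene that responds to glucocorticoids, rose by 0.47 (SE 0.09, adjusted p = 0.000477). The splicing factors Sfpq (0.45, adjusted p = 0.00375) and Tra2a (0.78, adjusted p = 0.0452) and the RNA granule gene Caprin1 (0.46, adjusted p = 0.0386) rose, while the list of cold-inducible and splicing RNA-binding genes as a whole gave no call (-0.08, adjusted p = 0.533). A second, dimmer Sfpq probe read only 0.08, and Tra2a lost its call with scan sessions blocked while keeping its size (0.72, adjusted p = 0.158). Ccdc117 (0.75, adjusted p = 0.00474) and the phospholipase gene Plcd4 (0.66, adjusted p = 0.0141) completed the genes higher in every region.

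Hes5 fell by 0.87 (SE 0.16, 1.82-fold, adjusted p = 0.000477) and Cirbp by 0.76 (SE 0.14, 1.69-fold, adjusted p = 0.000477), each in all 7 regions. Opalin, a membrane gene of myelinating cells, fell by 0.69 (SE 0.13, adjusted p = 0.000477), and Dbp fell by 0.49 (SE 0.09, adjusted p = 0.000477). Spata24 also fell in all 7 regions (-0.57, adjusted p = 0.0489), and with scan sessions blocked the call was lost at a similar size (-0.51, adjusted p = 0.112). Another 5 genes passed without the same sign in every region and are named here after their values were seen: the immediate early gene Egr2 (0.93, adjusted p = 0.00375, higher in 6 of 7; detected on 62 arrays and on no array of 10 groups, so its size is uncertain), the ubiquitin ligase Uhrf2 (0.53, adjusted p = 0.0047), Tm4sf4 (0.32, adjusted p = 0.0489, second probe 0.14), Dnajc30 (-0.26, adjusted p = 0.0216) and the RNA-binding gene Hnrnpdl (-0.94, adjusted p = 0.0047). Cdkn1a, Creld2, Egr2, Fam107a, Opalin and Tsc22d3 passed in all 27 alternative analyses, whereas the whole count dropped to 8 with median scaling and to 12 with 1 value per animal. Of the 20 genes, 8 kept their call with median scaling and 10 with 1 value per animal.

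**Figure D2:**
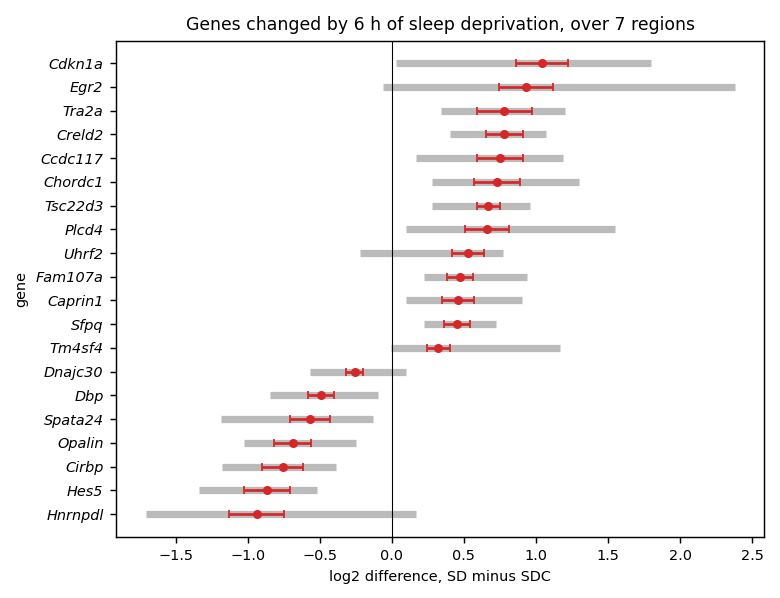
Log2 difference between deprivation and ZT6 controls (horizontal axis) for the 20 genes that passed. Red points are means over 7 regions with SE and grey bars run from the lowest to the highest region, as from 0.03 to 1.80 for Cdkn1a.

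Among genes named before the data were examined, Arc, the activity-regulated gene of dendrites, stood at 0.60 (SE 0.15) with an adjusted p of 0.068 over all genes, and it passed in 7 of 27 alternatives (adjusted p down to 0.0138). No call was made for the clock gene Per1 (0.01, adjusted p = 0.995), the ER chaperone Hspa5 (0.21, adjusted p = 0.787), Avp (0.24, adjusted p = 0.715) or Vip (0.22, adjusted p = 0.665). Avp was detected on 32 arrays and on no array of 23 groups, Vip on 72 arrays and on no array of 15 groups. Their means over regions thus hold many background values, and region values of Avp ran from -0.11 to 1.14. Of the transmitter genes, Hcrt (-0.34, adjusted p = 0.928) and Hdc (-0.09, adjusted p = 0.986) were saturated on arrays of the region that expresses them, where a change would be hard to see. No call was made for Dbh (0.14, adjusted p = 0.875), Th (0.01, adjusted p = 1) or Slc17a7 (0.06, adjusted p = 0.988). Th stood at 8.34 in the LC and between 6.49 and 6.70 elsewhere, and Dbh at 10.86 in the LC and between 9.71 and 9.99 elsewhere. Slc17a7 was highest in ENT, ORB and COApm. A mean over 7 regions thus dilutes changes where these genes are expressed. Region values ran from -0.13 to 0.47 for Dbh, -0.12 to 0.26 for Th and -0.32 to 0.36 for Slc17a7. Homer1 (0.04, adjusted p = 0.986) and Per2 (-0.04, adjusted p = 0.975) were detected on 13 and 7 arrays, so their values carry little. Fos and Pmch entered no test.

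Nearly all heat-shock genes stood higher after deprivation, and the lists of glucocorticoid targets, immediate early genes and ER chaperones stood higher on average. The heat-shock list (20 of 23 members measured) shifted by a mean of 0.22 (adjusted p = 2.72e-10, and adjusted p = 3.83e-05 with an estimated correlation), with 19 members above 0 and 1 below. Chordc1 was its only member to pass over all genes, while 5 members rose and 0 fell when adjusted over the list alone: Chordc1, Ahsa2 (0.56), Dnaja1 (0.36), Dnajb4 (0.30) and Hsp90ab1 (0.11). Glucocorticoid targets (21 of 25) shifted by 0.21 (adjusted p = 2.39e-08, and adjusted p = 2.37e-08 with an estimated correlation; 18 above 0, 3 below), with Cdkn1a and Tsc22d3 the 2 members that rose when adjusted over the list alone. The immediate early list (30 of 38) shifted by 0.16 (adjusted p = 6.6e-05, and adjusted p = 1.18e-05 with an estimated correlation; 21 above 0, 9 below), and Egr2, Arc, Egr4 (0.41) and Sik1 (0.53) rose when adjusted over the list alone, with 0 fallen. The ER list (20 of 25) shifted by 0.14 (adjusted p = 0.000929, and adjusted p = 0.000249 with an estimated correlation; 15 above 0, 5 below), with Creld2 and Dnajb11 (0.65) risen when adjusted over the list alone. Exact permutation of whole animals gave unadjusted p = 0.00379 for glucocorticoid targets and p = 0.0139 for heat shock, against p = 0.0846 for immediate early genes and p = 0.12 for ER chaperones. None of 145 such tests passed adjustment (adjusted p = 0.149, 0.288, 0.628 and 0.696 in that order).

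**Figure D3:**
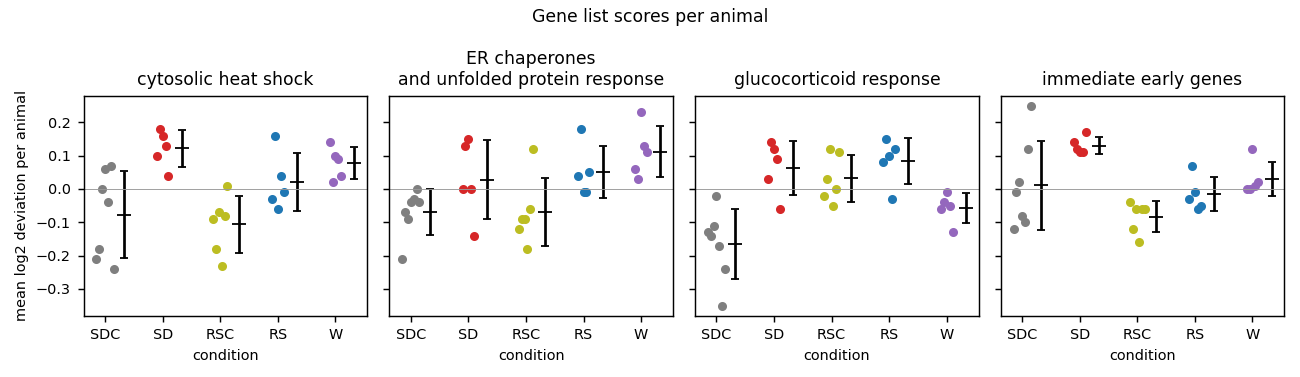
Mean list score of each animal (vertical axis, log2 relative to region means) by condition, with points for animals and black marks for mean and SD. Glucocorticoid targets stood at 0.07 in SD (5 animals) and -0.16 in SDC (7 animals). The lowest SDC scores, -0.35 and -0.24, came from animals with 1 array each.

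Oligodendrocyte genes (14 of 20) lay lower by 0.12 (adjusted p = 0.0124) and ribosomal protein genes (23 of 26) lower by 0.07 (adjusted p = 0.0211), but neither held with an estimated correlation (adjusted p = 0.136 and 0.357). Opalin was the only oligodendrocyte gene to fall when adjusted over the list alone. From other lists, Atf4 (0.25), the amino acid stress regulator, Tra2a (0.78) and the astrocyte enzyme Glul (0.20) rose and Dbp, Cirbp and Hnrnpdl fell when adjusted over the list alone. The remaining 22 lists had adjusted p between 0.14 and 0.878, among them neuron (shift 0.07), microglia (-0.07) and endothelial markers (-0.08), each at adjusted p = 0.215. Clock and astrocyte lists stood at adjusted p = 0.737.

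Deprivation calls within single regions were few, and small effects cannot be told from none with 4 against 4 arrays. In the SCh, Tsc22d3 rose 1.95-fold (0.96, SE 0.14, adjusted p = 0.00956) and the ubiquitin ligase Arih2 rose at least 1.79-fold (adjusted p = 0.00656), being detected on 0 of 4 control arrays. In the hypocretin area the RNA-decapping gene Dxo fell 2.16-fold (-1.11, SE 0.15, adjusted p = 0.0232), from 9.84 to 8.73. By limma no gene passed in LC, ENT, ORB, COApm or TMN, with 438, 367, 462, 255 and 413 genes at unadjusted p under 0.05. With scan sessions blocked these calls were lost, Tsc22d3 at 0.86 and Arih2 at 1.18 in the SCh (adjusted p = 0.834 each) and Dxo at an unmoved -1.11 (adjusted p just above 0.05).

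Lists showed more within regions than genes did. Immediate early genes were higher in ORB (shift 0.40, adjusted p = 0.00392, and adjusted p = 0.0183 with an estimated correlation) and TMN (0.22, adjusted p = 0.0158, and adjusted p = 0.0444 with an estimated correlation), the latter lost without the filter on dim probes (adjusted p = 0.131). ER chaperones were higher in ENT (0.39, adjusted p = 0.00397, and adjusted p = 0.0358 with an estimated correlation), but not with slide series or scan sessions blocked (adjusted p up to 0.0967), and general neuron markers stood 0.34 higher there without a call (adjusted p = 0.383). Neuron markers were higher in COApm (0.35, adjusted p = 0.00803, and adjusted p = 0.0466 with an estimated correlation), a call lost without the filter on dim probes (adjusted p = 0.0815). Calls that an estimated correlation did not keep were heat shock in LC (0.43, adjusted p = 3.71e-05, then 0.0955), ENT (0.44, adjusted p = 6.54e-05, then 0.0956), SCh (0.29, adjusted p = 0.0198, then 0.424) and TMN (0.17, adjusted p = 0.0205, then 0.43). Glucocorticoid targets in the hypocretin area (0.26, adjusted p = 0.00737, then 0.0702) and SCh (0.36, adjusted p = 0.0198, then 0.391) were not kept, nor were ER (0.38, adjusted p = 0.0155, then 0.134) and integrated stress genes (0.25, adjusted p = 0.00769, then 0.134) in LC or immediate early genes in ENT (0.35, adjusted p = 0.0456, then 0.0956). In ORB, neuropeptides (0.17, adjusted p = 0.037, then 0.294), oxidative phosphorylation (-0.17, adjusted p = 0.037, then 0.38) and oligodendrocyte genes (-0.22, adjusted p = 0.0256, then 0.294) were not kept either.

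The response of Arc to deprivation gave the largest F statistic for a difference between regions. A test of the 7 regional effects against each other passed for 3 genes (597 at unadjusted p under 0.05), Arc among them (F = 7.47, adjusted p = 0.00828). Arc was higher after deprivation by 1.97 in ENT, 1.54 in ORB and 1.5 in COApm (SE 0.40 each), while it stood at 0.32 in TMN, 0.24 in LC, -0.49 in the hypocretin area and -0.85 in the SCh. It was detected on 1 of 4 arrays in each LC group and on 2 of 4 deprived SCh arrays, so those values lie partly at background. The transcription factor Irx4 (F = 7.33, adjusted p = 0.00828) rested on LC (-1.42), the only region where it was detected, and Tm4sf1 (F = 6.36, adjusted p = 0.0383) was higher in LC (1.87) and lower in TMN (-0.97, detected on 1 of 4 deprived arrays). As a list, immediate early genes ran from -0.05 in SCh to 0.36 in ORB, and their regional difference had permutation p = 0.00869 (adjusted p = 0.252). Chance cannot be excluded for the count of 3, as 67 of 100 splits of the animals gave as many, and with an offset of 16 the count was 0 (Arc adjusted p = 0.073). The Arc call was also lost without deprived animal 1 (adjusted p = 0.179) or 3 (adjusted p = 0.145), among 24 alternatives.

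**Figure D4:**
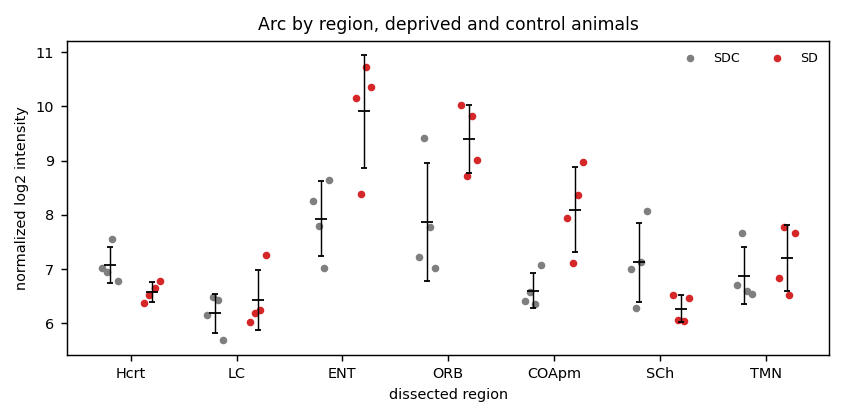
Arc expression (log2 intensity, vertical axis) in each region after deprivation and in ZT6 controls, with points for arrays and black marks for mean and SD. The gap was 1.97 in ENT, 1.54 in ORB and 1.5 in COApm, and reversed in sign in the SCh at -0.85.

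Recovery sleep left few traces after 4 h. Heat-shock and ER chaperone lists were still high, while no single gene differed from RSC across regions. The limma count was 0, with 496 genes at unadjusted p under 0.05 where chance gives 599. Dbp came nearest (-0.39, SE 0.09, unadjusted p = 3.83e-05, adjusted p = 0.418), lower in all 7 regions.

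Heat-shock genes stood higher by 0.15 after recovery (adjusted p = 0.000135, and adjusted p = 0.0279 with an estimated correlation; 16 above 0, 4 below), and the inducible Hsp70 gene Hspa1a (0.71, adjusted p = 0.00734) was the 1 member that rose, with 0 fallen, when adjusted over the list alone. ER chaperones stood higher by 0.16 (adjusted p = 0.00648, and adjusted p = 0.00424 with an estimated correlation), with 0 members risen or fallen when adjusted over the list alone, and without recovery animal 2 the adjusted p was 0.0674. Exact permutation of animals gave unadjusted p = 0.0303 for heat shock (adjusted p = 0.428) and p = 0.0584 for ER chaperones (adjusted p = 0.517). The smallest exact permutation p was that of glutamate receptors and postsynaptic proteins, higher by 0.09 with all 5 recovery animals above all controls (p = 0.00433, adjusted p = 0.149). From other lists, Plin4 (0.46) and Slc1a2 (0.50) rose and Dbp and Opalin (-0.42) fell when adjusted over the list alone. Glucocorticoid, oxidative stress and oxidative phosphorylation lists each had adjusted p = 0.052, with 0.048, 0.109 and 0.379 under an estimated correlation, so the glucocorticoid call depends on that choice, and the rest lay between 0.145 and 0.988.

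Single regions gave 1 gene after recovery, the zinc finger gene Zfp106, which fell in ENT (-1.81, SE 0.24, adjusted p = 0.00662). It was detected on 1 of 4 recovery arrays and 4 of 4 controls, so the size of the fall is uncertain. By limma no gene passed in the hypocretin area, LC, ORB, COApm, SCh or TMN, with 269, 324, 608, 221, 298 and 259 at unadjusted p under 0.05. Heat-shock genes were higher in ORB (0.35, adjusted p = 0.000164, and adjusted p = 0.0108 with an estimated correlation). In the hypocretin area ER (0.33, adjusted p = 0.0162), heat-shock (0.21, adjusted p = 0.0467) and glucocorticoid lists (0.27, adjusted p = 0.0162) were not kept with an estimated correlation (0.371, 0.575 and 0.157), nor were glucose genes in ORB (0.37, adjusted p = 0.0129, then 0.187) or ribosomal genes in TMN (-0.19, adjusted p = 0.0302, then 0.839).

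A smaller effect after recovery sleep than after deprivation was called for Tsc22d3 alone, and chance cannot be excluded for it. Its deprivation effect exceeded its recovery effect by 0.52 (SE 0.11, adjusted p = 0.0421), at 0.67 against 0.15, while the ZT10 controls stood 0.32 above the ZT6 controls, and no other gene passed among 582 at unadjusted p under 0.05. As many calls came from 11 of 100 splits of the animals, and the call was absent with median scaling, with a smaller background offset, with scan sessions blocked, with 1 value per animal, and without the pooled, the dimmest or the Slc6a2-carrying arrays. No list differed between the effects (adjusted p from 0.108 to 0.985), so chaperone genes were not shown to have declined with sleep.

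Spontaneous waking at night shared 5 genes and its chaperone lists with deprivation, in part against the same ZT6 control arrays. Creld2, Sfpq and Egr2 were higher and Opalin and Dbp lower in both, although waking at ZT18 also differs from its ZT6 and ZT10 controls by time of day. The falls of Dbp were spread differently over regions. Waking moved it by -1.69 in the SCh and by a mean of -0.14 in the other 6 regions. Deprivation lowered it in all 7 regions, in the SCh from 13.86 to 13.66. Across regions 11 genes passed against the controls, 6 higher and 5 lower (656 at unadjusted p under 0.05), and 7 higher and 0 lower with median scaling.

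Creld2 rose 1.71-fold (0.77, SE 0.12, adjusted p = 1.2e-05) and Sfpq 1.42-fold (0.50, SE 0.08, adjusted p = 2.41e-05, with the second probe at -0.11), and these 2 passed in all 33 alternative analyses. The Hsp40 gene Dnaja1 (0.45, adjusted p = 0.0289), the splicing gene Rbm10 (0.26, adjusted p = 0.0143) and the neuronal transcription factor Sox11 (0.68, adjusted p = 0.025) rose, Sox11 keeping its size but not its call with scan sessions blocked (0.68, adjusted p = 0.0605) and reading 0.15 on a second probe. Opalin fell by 0.64 (SE 0.11, adjusted p = 0.00025), and the calcium-binding gene S100a16 (-0.28, adjusted p = 0.0253) and the class Ib histocompatibility gene H2-M1 (-0.32, adjusted p = 0.0253) were lower in every region. Of the 33 alternatives, S100a16 lost its call in 12, Dnaja1 in 11 and H2-M1 in 10. Dbp fell by 0.36 (adjusted p = 0.0143), which rested on the SCh. Named after their values were seen, Egr2 rose (0.87, adjusted p = 0.00198, with the same limit of detection) and Fabp7, a fatty-acid carrier of astrocytes that cycles over the day, fell (-0.70, adjusted p = 0.00198). Cirbp was not called (-0.24, adjusted p = 0.904). The count was 5 without waking animal 1, 6 without waking animal 4, 7 without waking animal 3, ZT6 control animal 1 or ZT10 control animal 4, and 6 with 1 value per animal, but 17 with scan sessions blocked or arrays weighted.

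ER chaperones shifted by 0.20 in waking (adjusted p = 6.53e-07, and adjusted p = 9.5e-08 with an estimated correlation; 16 above 0, 4 below), and Creld2, Dnajb11 (0.44), Manf (0.32), Pdia3 (0.45) and Pdia4 (0.40) rose, with 0 fallen, when adjusted over the list alone. Heat-shock genes shifted by 0.19 (adjusted p = 1.04e-09, and adjusted p = 0.000108 with an estimated correlation; 17 above 0, 3 below), and Ahsa1 (0.41), Dnaja1, Dnajb4 (0.18), Hspa1a (0.49) and Hspb1 (0.57) rose, with 0 fallen, when adjusted over the list alone. Exact permutation of animals gave p = 0.000584 for ER (adjusted p = 0.0846) and p = 0.00514 for heat shock (adjusted p = 0.149). Oligodendrocyte genes had adjusted p = 0.0736 and the other lists between 0.366 and 0.971. Atf4 (0.19) and Tra2a (0.67) rose when adjusted over the list alone.

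Deprivation and waking could be compared without shared controls by setting SD against SDC and W against RSC. Of the 13 genes higher and 7 lower after deprivation, 3 (Creld2, Egr2, Sfpq) were among the 6 higher in waking and 2 (Dbp, Opalin) among the 2 lower, with 0.00651 and 0.00117 shared genes expected by chance. Dbp in RSC stood 0.38 above SDC, without a call, so its fall in waking against RSC also holds that difference. The overlap of 5 was 1 with median scaling and 1 with 1 value per animal, and 3 at the fewest when an animal was left out. In sign, 18 of the 20 deprivation genes matched in waking and 17 of 20 in recovery sleep.

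Glucocorticoid targets, immediate early genes and Fabp7 stood higher in deprivation at ZT6 than in spontaneous waking at ZT18. Deprivation and time of day cannot be told apart in this comparison. Fabp7 was higher by 1.02 (SE 0.15, 2.03-fold, adjusted p = 1.86e-05), beside its fall in waking, and it was not called for deprivation against SDC. Across regions 5 genes passed, 2 higher and 3 lower (710 at unadjusted p under 0.05), and none with median scaling.

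Rcn1, a calcium-binding gene of the ER, was lower (-0.59, SE 0.12, adjusted p = 0.0134; -0.54 with scan sessions blocked, adjusted p = 0.111), as were the inositol phosphatase Inpp5k (-0.40, adjusted p = 0.0339, second probe -0.04) and Tmem179 (-0.25, adjusted p = 0.0159). Cdkn1a, outside the naming rule, was higher by 0.88 (SE 0.18, adjusted p = 0.0134). Calls were lost for Inpp5k in 11 of 25 alternatives, for Cdkn1a and Tmem179 in 7 each and for Rcn1 in 6. Cirbp (-0.60, adjusted p = 0.053, passing in 7 of 25 alternatives), Avp (0.42, adjusted p = 0.136) and Dbp (-0.32, adjusted p = 0.228) were not called over all genes. The count was 1 without waking animal 4, 2 without waking animal 1, 3 without waking animal 5 or deprived animal 2 or 4, 8 without deprived animal 3 or with slide series blocked, 10 with array weights, 13 with scan sessions or the detected share taken into account, and 1 with 1 value per animal.

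Glucocorticoid targets were higher after deprivation than in waking by 0.14 (adjusted p = 0.000165, and adjusted p = 5.5e-05 with an estimated correlation), with Cdkn1a and Tsc22d3 (0.32) risen and 0 fallen when adjusted over the list alone. Immediate early genes were higher by 0.10 (adjusted p = 3e-04, and adjusted p = 5.5e-05 with an estimated correlation), with Crem (0.54) and Sik1 (0.59) risen and 0 fallen when adjusted over the list alone. Markers of the suprachiasmatic nucleus were higher by 0.10 (adjusted p = 0.00399, and adjusted p = 0.00539 with an estimated correlation), with Avp the 1 member risen when adjusted over the list alone, though scan sessions as blocks gave adjusted p = 0.0536. That call rested on the SCh, since the other 6 regions alone gave a shift of 0.06 (adjusted p = 0.121), with Avp at 0.08. Dbp, Tef (-0.29), Cirbp and Hnrnpdl (-0.55) were lower when adjusted over the list alone, and other lists lay between 0.104 and 0.989. By exact permutation of animals the cold-inducible list was lower by 0.15 (p = 0.00794, all 5 deprived animals below all 5 waking ones), the glucocorticoid and immediate early lists had p = 0.0317 each, and no adjusted p was under 0.05.

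Undisturbed mice differed little between ZT6 and ZT10, apart from glucocorticoid targets. These stood higher at ZT10 by 0.14 (adjusted p = 0.00631, and adjusted p = 0.0048 with an estimated correlation; 14 above 0, 7 below), at a time when corticosterone is known to climb toward evening. Nfkbia (0.55), Plekhf1 (0.65) and Tsc22d3 (0.32) were the 3 members that rose, with 0 fallen, when adjusted over the list alone. By limma no gene passed over all genes (361 at unadjusted p under 0.05), Dbp reaching 0.38 (adjusted p = 0.315). Dbp and Usp2 (0.42), both driven by the clock, rose when adjusted over the list alone, and other lists lay between 0.299 and 0.93. Without ZT10 control animal 3 the glucocorticoid list had adjusted p = 0.213.

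**Figure D5:**
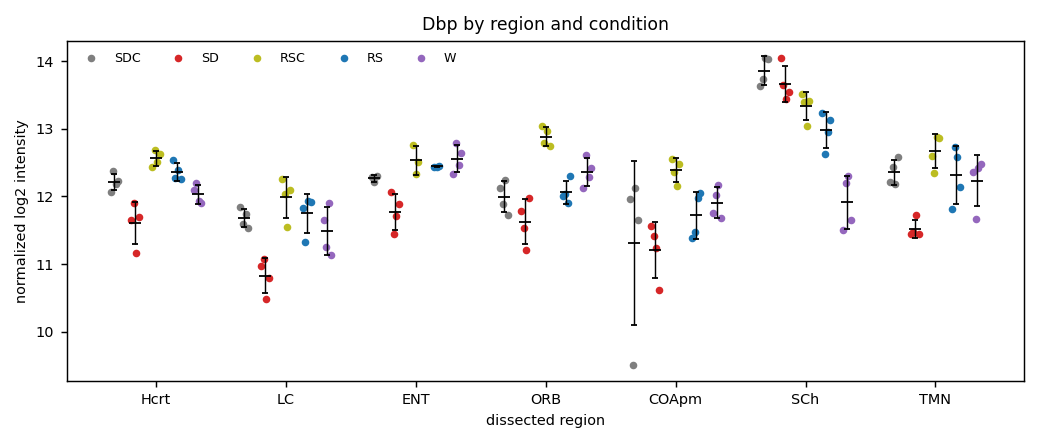
Dbp expression (log2 intensity, vertical axis) by region and condition, with points for arrays and black marks for mean and SD. Deprivation lowered Dbp by 0.49 over regions, and in the SCh waking stood at 11.91 against 13.86 at ZT6.

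Probes without a gene name were tested apart from named genes. Among 16279 such probes, 5 were higher and 2 lower after deprivation (838 at unadjusted p under 0.05), 1 was higher against waking (882), and none passed for recovery sleep (642), waking against controls (851) or time of day (508).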

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

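The tests of technical explanations and the counts over other splits of the animals were chosen after the results were seen. Among 35 groups of animal list scores, 2 held an animal far from the others, and chance picks about 1 group in 20. The immediate early score of 1 waking animal was 0.12 where the other 4 lay between 0.00 and 0.02 (gap 0.828 of the range). The suprachiasmatic marker score of 1 ZT6 control animal was -0.33 where the others lay between -0.05 and 0.07 (gap 0.686 of the range). That animal gave 1 array, from the SCh, so its score was not averaged over regions as that of most others was. No array stood out by detected share in 35 groups, nor by the genes called in single regions in 8 groups.

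Differences between groups drew attention to 4 genes. Arc (F = 7.47), Irx4 (F = 7.33) and Tm4sf1 (F = 6.36) differed between regions in their deprivation effect. Tsc22d3 differed by 0.52 between its deprivation and recovery effects. Among probes without a gene name, which the report's gene comparisons do not use, 7 passed for deprivation against ZT6 controls and 1 for deprivation against waking.

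Heat-shock and ER chaperone lists stood higher in deprivation, recovery sleep and waking. Differences between scan sessions as the whole cause are argued against, since the 6 list shifts stayed between 0.14 and 0.23 (highest adjusted p = 0.0265) with sessions blocked, and heat-shock genes were higher within all 10 deprivation sessions, all 9 recovery sessions and all 11 waking sessions (ER genes in 8, 9 and 11). Brighter arrays are argued against as well, the shifts staying between 0.13 and 0.20 (highest adjusted p = 0.0107) with the detected share of each array as a covariate. Waking may raise chaperones, a hypothesis that was not tested further and that leaves their level after recovery sleep unaccounted for. Handling of the animals and the time of day of waking stay open, as the design confounds them with the conditions.

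Opalin fell after deprivation by 0.69. A smaller share of oligodendrocytes is argued against, because 12 other abundant oligodendrocyte genes had a median change of -0.06 (range -0.36 to 0.22, SD 0.16). Scan sessions are argued against by a change of -0.66 (adjusted p = 0.00166) with sessions blocked, lower in 9 of 10 sessions. Opalin also fell in spontaneous waking (-0.64, adjusted p = 0.00025), where no sleep was withheld but the time of day differed from that of the controls. In recovery sleep it stood at -0.42, without a call over all genes (adjusted p = 0.771), in mice that had also been deprived. Whether the fall is tied to lost sleep is thus left open, and no biological explanation was tested.

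Other splits of the animals tested whether a chance division of animals can be excluded for each count of genes. Deprivation across regions was matched by 1 of 100 splits, the real one (20 genes, highest other 15). Deprivation against waking was likewise matched by the real split alone (1 of 100, 5 genes, highest other 1). A chance division is thus unlikely for these counts but not excluded. The share is the smallest that 100 splits can give, and it was read without adjustment over the counts. Waking against controls was matched by 2 of 100 (11, highest other 14), and since a chance split gave more genes than the real one, its count is left in doubt. For the difference between deprivation and recovery effects, chance cannot be excluded (11 of 100 splits, 1 gene, highest other 4). Nor can it be for the regional differences (67 of 100, 3 genes, highest other 81, a count whose cause was not tested). Counts of 0 were matched by every split, in 100 of 100 for recovery sleep (highest other 15) and for time of day (highest other 3). In single regions, only the real split reached the count for deprivation in the SCh (1 of 35; 2 genes, highest other 1) and recovery in ENT (1 of 35; 1 gene, highest other 0). This is the smallest share that 35 splits can give, it was read over 14 regional counts without adjustment, and both counts were 0 with slide series blocked, so these calls stay doubtful. Waking in the SCh was matched by 1 of 100 splits (8 genes, highest other 3), in a region chosen after its values were seen. Chance cannot be excluded for deprivation in the hypocretin area (11 of 35; 1 gene, highest other 6). All other regional counts were 0 and were matched in 35 of 35 splits. The highest other counts for deprivation were 10 in LC, 3 in ENT, 13 in ORB, 1 in COApm and 1 in TMN. For recovery they were 2 in the hypocretin area, 2 in LC, 1 in ORB, 2 in COApm, 1 in the SCh and 142 in TMN. The ORB split with 13 genes followed the scan sessions exactly, and what lay behind the TMN split with 142 genes was not tested. These splits were not refitted with sessions blocked.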

How the results depend on the processing

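The tests with scan sessions as blocks, without the dimmest arrays, without arrays with locus coeruleus signal, with the detected share as a covariate and with draws of genes for the animal correlation were chosen after the data were seen. No result reversed. Counts of genes stayed within 1.5 times their value in 414 instances and moved further in 107, and for the SCh at night in 2 and 19. Lists across regions kept their side of the threshold in 367 instances and lost it in 16, and lists within single regions kept it in 150 and lost it in 48. Tests of single genes kept their side in 2836 instances, lost significance in 349 and gained it in 15, of which Arc for deprivation and Cirbp against waking made up 7 each and Dbp in recovery 1 (array weights, adjusted p = 0.0198). The instances kept include genes of interest that had no call to lose, some of them detected on few arrays. Among called genes the share of calls lost was therefore larger than these totals give. The heat-shock (0.19 to 0.26), glucocorticoid (0.19 to 0.24), immediate early (0.14 to 0.21) and ER lists (0.11 to 0.18) kept their call for deprivation in all 27 alternatives. Where a count moved, the cause was not tested, except that leaving out samples or averaging to animals leaves fewer values. The deposited table of processed values was tried under its column names, gave counts that could not be used because its columns did not match the arrays they are named for, and was left out. Array medians of signal between 9.4 and 62.4 against a local background of 44 to 57 limit what can be seen of dim genes.

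The animal correlation had come from draws of genes before all tested genes were used. The first draw gave 25 genes for deprivation (14 higher, 11 lower) and 12 for waking, the second 20 and 11, and 10 draws gave correlations of 0.00547 to 0.00935, with 18 to 25 genes for deprivation, 11 to 12 for waking and 5 for deprivation against waking. All 20 deprivation genes were kept in both draws.

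With an offset of 16, counts were 0 for the difference between deprivation and recovery effects, 0 for regional differences, 0 for deprivation in the hypocretin area and 1 in the SCh. With median scaling they were 8 for deprivation (6 higher, 2 lower), 1 for recovery, 7 for waking, 0 for deprivation against waking, 0 for the difference of effects, 1 for the overlap, 1 for regional differences, and 0 for deprivation in the hypocretin area and in the SCh, and the oligodendrocyte shift was -0.09 (adjusted p = 0.101). With slide series blocked, counts were 8 for deprivation against waking, 0 for recovery in ENT and 0 for deprivation in the SCh. With scan sessions blocked, they were 17 for waking (10 higher, 7 lower), 13 for deprivation against waking, 0 for the difference of effects, 6 for regional differences, 0 for deprivation in the hypocretin area and 0 in the SCh, and the suprachiasmatic marker shift between deprivation and waking was 0.06 (adjusted p = 0.0536). Array weights gave 1 for recovery, 17 for waking, 10 for deprivation against waking, 1 for regional differences and 2 for recovery in ENT. A single fit of all 140 arrays gave for deprivation 4 genes in the hypocretin area, 9 in LC, 3 in ENT, 7 in ORB, 4 in the SCh and 1 in TMN, and for recovery 1, 2, 2, 2, 1 and 6 in the hypocretin area, LC, ENT, ORB, COApm and TMN.

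With an estimated correlation the ribosomal shift of -0.07 had adjusted p = 0.357 and the oligodendrocyte shift of -0.12 had 0.136. Without the 3 pooled arrays the oligodendrocyte and myelin shift across regions, SD vs SDC, was -0.1 (adjusted p above 0.05), the difference of effects 0 and regional differences 5. Without the dimmest arrays the difference of effects was 0, and so it was without arrays with locus coeruleus signal, where deprivation gave 18 genes and waking 11. The detected share as a covariate gave 13 for deprivation against waking. With 1 value per animal, counts were 12 for deprivation (8 higher, 4 lower), 6 for waking, 1 for deprivation against waking, 0 for the difference of effects and 1 for the overlap. Of the genes called in the main fit, 10 of 20 were kept for deprivation, 6 of 11 for waking and 1 of 5 for deprivation against waking.

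Leaving out each animal in turn gave 15 to 24 genes for deprivation, 5 to 14 for waking, 1 to 8 for deprivation against waking, 0 to 1 for recovery, for time of day and for the difference of effects, 0 to 5 for regional differences and 3 to 5 for the overlap. List shifts ran from -0.11 to -0.02 for ribosomal genes (call lost in 6 of 12), from -0.15 to -0.08 for oligodendrocyte genes (lost in 3 of 12), from 0.14 to 0.17 for ER genes in recovery (adjusted p = 0.0674 without RS animal 2) and from 0.11 to 0.16 for glucocorticoid targets by time of day (0.213 without RSC animal 3). Leaving out single replicates in regions gave, for deprivation, 0 to 2 genes in the hypocretin area, 0 to 1 in LC, 0 to 1 in ORB and 1 to 5 in the SCh, and for recovery 0 to 1 in the hypocretin area, ORB, COApm, the SCh and TMN and 0 to 2 in ENT. Of single genes, Spata24 lost its call in 18 of 27 alternatives, Tra2a in 17, Tm4sf4 in 15, Dnajc30 in 13 and Caprin1 in 10. Between 14 and 19 of the 20 deprivation genes were kept when an animal was left out.

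The replicate block, the decade of the specimen number, gave 20 genes for deprivation, 13 for waking and 7 for deprivation against waking, and 0 for the difference of effects and for deprivation in the SCh. As a check of pairing, what remained after removing group means was correlated between arrays of the same region and different conditions. Arrays sharing that decade correlated at a mean r of 0.133 over 244 pairs (lowest -0.196), with 147 pairs above 0.1. Pairs of different decades gave -0.0366 over 876 pairs, with 88 above 0.1. Arrays sharing a scan session correlated at 0.164 (lowest -0.188), against -0.0393 for other sessions. Sharing either thus went with correlation, but not in every pair, which the criterion for pairing asked, so no paired analysis was made the main one. The main fits hold no block for decade or session, so this correlation stays in their spread. Where conditions were not balanced over sessions it also enters the differences, and the p values of the main fits do not cover that part. In ENT, for example, deprived arrays were scanned in sessions 4, 6 and 9 and their controls in sessions 1, 3, 7 and 9.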

Other observations

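All tests of the SCh at night and of the Hdc signal were chosen after the values were seen. The suprachiasmatic region changed in Dbp and Nnmt with the night. In spontaneous waking at ZT18, Dbp fell 3.22-fold there against the light-phase controls (-1.69, SE 0.17, adjusted p = 0.000155), from 13.86 at ZT6 and 13.34 at ZT10 to 11.91. This gene is a direct output of the clock, and its mean change in the other 6 regions was -0.14. The difference of -1.54 had permutation p = 1e-05, the smallest these permutations can give, for a gene of interest named beforehand in a region picked from 7 after its values were seen. Nnmt, which methylates nicotinamide, fell 7.94-fold (-2.99, adjusted p = 0.00882). Rasd1, a small G protein of the clock nucleus, rose by 1.20 (adjusted p = 0.049), and the kelch gene Klhdc8a rose by 1.31 (adjusted p = 0.049).

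The neuroendocrine granule gene Chga (-0.79), the immediate early gene Nr4a1 (-0.85, detected on 1 of 4 waking arrays), Arf1 (-1.82) and Gfer (-1.15) fell, each at adjusted p = 0.049. In all, 8 genes passed in the SCh, 2 higher and 6 lower, with 894 at unadjusted p under 0.05. Whether these genes, other than Dbp, changed more in the SCh than elsewhere was not tested free of their selection. Against waking, deprivation in the SCh gave 3 genes higher and 1 lower (592 at unadjusted p under 0.05): Dbp (1.75, adjusted p = 0.000759), Arih2 (adjusted p = 0.00159, detected on 0 of 4 waking arrays, so without a fold), Nr4a1 (1.11, adjusted p = 0.0215) and Rasd1 (-1.84, adjusted p = 0.00299). Dbp and Nnmt passed in 19 of 21 alternatives, Gfer in 4, Arf1, Chga, Nr4a1 and Rasd1 in 2 each and Klhdc8a in 1, so little beyond Dbp and Nnmt held. The count of 8 fell to between 1 and 4 under other settings and ran from 1 without waking replicate 3 to 19 without waking replicate 1.

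Hdc, which marks histamine neurons, stood at 10.97 in the SCh on all 20 arrays (10.1 to 11.95), at most 7.57% of its linear level in the TMN, where 8 arrays were saturated. Cross-hybridisation of the probe to a common transcript is argued against, since the highest mean among the 5 remaining regions was 6.80. Carry-over of tuberomammillary tissue or RNA was examined through 9 other genes of the TMN (Col6a2, Maob, Nfatc4, Otop3, Prph, Slc13a4, Sulf1, Tbx3 and Wnt9b), after stricter limits on level and detection had given no gene and were lowered. Their median change in the SCh was -0.18 against 0.50 at most for such carry-over, and all 9 lay below their own expected level. The gap between measured and expected level had a spread of 0.71 among the genes, and the expected level is an upper bound, so carry-over is left open. No biological explanation was tested.

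The deposited table of processed values named its columns for the 140 arrays, yet only 3 columns were closest to the array of the same name. The nearest other column came from the same region for 32 of 140 columns, while among the scanner files the nearest other array did so for 133 of 140. The table was not used here.

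Arrays outside the LC with Slc6a2 over 8 numbered 6. An array of the ZT10 controls of the hypocretin area (replicate 4) stood furthest, with Slc6a2 at 11.31 where its group lay between 5.85 and 6.04, Hdc at 8.17, and list scores of 0.89 for LC markers, 0.83 for tuberomammillary markers and -1.02 for hypocretin area markers. The others were at 9.96 (COApm, ZT6 control 4), 8.89 (COApm, ZT10 control 3), 8.70 (TMN, recovery 4), 8.50 (hypocretin area, deprivation 4) and 8.24 (ORB, recovery 3). Recovery in the hypocretin area gave 0 genes with and without these arrays.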
